A study of Homo sapiens with 10 samples.

How the data were processed

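The data were 10 RNA-seq libraries of human brain endothelial cells, 5 with a control siRNA and 5 with an siRNA against USP9X, all with Wnt3a. Samples were grouped by the treatment label and numbered by the replicate number in their titles. The deposited table holds counts of whole numbers per gene symbol, not normalized, with 1 column per library. Per the labels' protocols, RNA was extracted with TRIzol and made into stranded poly(A) mRNA libraries. The submitters' processing notes name hg38, RSEM and DESeq2, with no version, role or order. Whether the whole numbers are rounded RSEM estimates, and which aligner and annotation the authors used, is not given in the sources used here. If they are rounded estimates, reads shared between similar genes were split between them before deposit.

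The table has 58735 lines and 57167 distinct symbols. Symbols shared by several lines (1745 lines) were kept apart, and 27 lines with date-like symbols, holding 0.253% of all counts, were kept under the symbol in the table. Symbols were matched to GENCODE release 29 (GRCh38), where 56923 lines (96.91%) matched exactly 1 gene, and coordinates come from that annotation. Y-linked genes and XIST are not printed. Totals ran from 15.96 to 26.47 in units of 1e+06 counts. Replicates of a group differed by more than sampling noise in every pair, with at least 5.31 chi-square per degree of freedom, so none looked like 1 library sequenced in parts. Each library counted as 1 replicate, though this check cannot tell separate cultures from repeated preparations of 1 culture.

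Genes were tested with the edgeR quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest, edgeR 4.0.16, R 4.3.3) on the counts as deposited, with TMM factors, the filterByExpr filter with its minimum count of 10, and group as the only term. P-values are two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. CPM are counts per 1e+06 counts of the library total scaled by its TMM factor. Pooled counts of low genes carry exact Poisson intervals at 95%, which cover counting error only. 28 gene lists with 628 distinct genes were fixed before the data were examined, as were the main test, its alternatives and the rule for the genes named. The lists cover Wnt targets and Wnt components, blood-brain barrier, junction, fenestration and caveola, endothelial, tip cell, Notch, TGF-beta and BMP, mesenchymal, YAP/TAZ, inflammation, interferon, G1/S, G2/M, p53, stress response, proteasome, deubiquitinase, cholesterol, glycolysis and matrix genes, and markers of mural, fibroblast, neural, immune, epithelial and lymphatic cells. Each list was counted with p adjusted over all tested genes and adjusted over the list alone, and tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one. No camera call held with the estimated correlation, where the lowest adjusted p was 0.0869. Lists were also tested with fry (limma), planned beside camera, which does not compare members with other genes. The fry adjusted p for a shared direction was lowest for G1/S genes and epithelial markers (2.09e-05). Values of fry are given below for Wnt, barrier, junction, caveola, mesenchymal and matrix genes. For lists that camera did not call at the preset correlation, these include every fry call for a shared direction. For changes in either direction, fry also passed the threshold for tip cell, Notch, G2/M, p53, stress response and glycolysis genes (adjusted p of 0.0258 or lower).

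The genes named were USP9X, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, up to 4 members per list with the smallest p, 19 Wnt and barrier genes in any case, and the 3 increases and 3 decreases with the smallest p. Some genes that this rule selects are not reported here. Genes outside this rule are said to be chosen after their values were seen. Annotated 3′ UTRs of 11904 tested genes were searched for all 7-base words found in at least 50 of them (16228 words). The mean log2 fold change of genes with a word was adjusted for UTR length, GC content and mean CPM and compared with 100 shuffles of the fold changes over genes.

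Alternatives were DESeq2 size factors, upper-quartile factors and library totals, no filter, a filter of 5 CPM in 5 libraries, DESeq2 1.42.0, limma-voom, the replicate block, 1 surrogate variable (sva 3.50.0), a threshold of 0.01, a minimum absolute log2 fold change of 1, and each library left out in turn. Offsets for transcript length and GC content, library weights, the block without replicate number 2, and counts without the genes that hold the 4 words were added after the data were seen. On counts simulated for the real genes and library sizes, the main test recovered 12 of 67 genes changed 1.5-fold, 43 of 67 changed 2-fold and 63 of 66 changed 4-fold, and called 8 of 13709 unchanged genes. In the same simulation limma camera, a model-based and not an exact test, gave p = 3.05e-09 for a planted list and 0.537 for a random one. Genes were drawn independently there and no library was made to stand apart, so camera was not tried on correlated genes. In the data the estimated correlations ran from -0.126 for epithelial markers to 0.335 for endothelial genes. The word scan recovered 20 of 20 words planted with a log2 decrease of 0.13 into shuffled fold changes. This size is that of the most negative word in the data, and the planted words were about as common. The check therefore shows that such an effect can be found, and does not measure how often the real data give false words. Scans and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.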

Results

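RNA was sequenced from human brain endothelial cells, labelled HCMECs and recorded as a cell line, in 10 libraries. In 5 of them the cells had received a control small interfering RNA (siCtrl), and in the other 5 an siRNA against USP9X (siUSP9X), a deubiquitinase that removes ubiquitin from target proteins. The cells of all 10 libraries were given Wnt3a, a ligand of the Wnt/beta-catenin pathway, for 12 h after 48 h of transfection. No unstimulated cells were analysed here, so every difference below is between siUSP9X and siCtrl cells in the presence of Wnt3a. The question named by the study's title is whether USP9X acts on Wnt signalling and on the barrier genes of brain vessels. Library totals were 18739639, 18670340, 17716250, 26467787 and 18786854 counts in siCtrl replicates 1 to 5, and 16572577, 20442278, 16490674, 15958362 and 16898285 counts in siUSP9X replicates 1 to 5. The labels do not say whether the 5 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

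USP9X mRNA (ENSG00000124486.12, chromosome X, 41085635 to 41236579, plus strand, GRCh38) was 9.68-fold lower in siUSP9X cells. It averaged 341 ± 48.6 CPM (SD, n = 5, CPM being counts scaled to library size) in siCtrl and 35.2 ± 19.8 CPM (SD, n = 5) in siUSP9X, a log2 fold change of -3.28 ± 0.32 (SE, edgeR adjusted p = 0.000403). Every siUSP9X library lay below every siCtrl library. The highest siUSP9X value was 68.8 CPM, in replicate 2, and the lowest siCtrl value was 283 CPM. Of 38 other deubiquitinases measured, USP48 rose (log2 fold change 0.47 ± 0.13), BAP1 and USP11 fell (-0.47 ± 0.10 and -0.41 ± 0.09, SE), and 35 did not pass the threshold. Leaving out siUSP9X replicate 2 gave 4 higher and 6 lower, and leaving out another library 0 to 2 of each. USP48, USP11 and BAP1 kept their calls in 2, 5 and 8 of the 10 fits that left out 1 library.

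**Figure D1:**
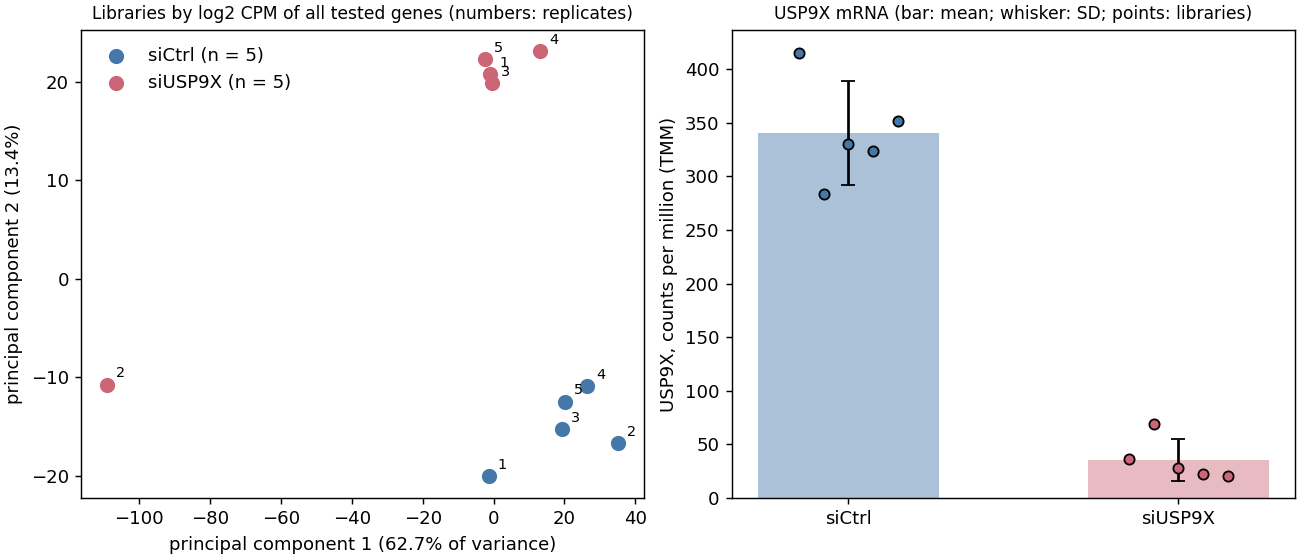
Left, the 10 libraries (points, with replicate numbers) on the first 2 principal components of log2 CPM over all tested genes, where component 1 (62.7% of the variance) sets siUSP9X replicate 2 apart and component 2 (13.4%) holds the other 4 siUSP9X libraries above the 5 siCtrl libraries. Right, USP9X in CPM per library (points), with the group mean (bar) and SD (whisker), 341 in siCtrl and 35.2 in siUSP9X.

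Among 13934 tested genes, 570 were higher and 449 lower in siUSP9X cells at an adjusted p under 0.05 (edgeR quasi-likelihood test). The log2 fold change was at least 1 for 136 of the higher genes and at most -1 for 80 of the lower genes. The groups did not overlap for 2041 genes, 1086 with all siUSP9X libraries above and 955 with all below, or 14.6% of tested genes against 0.794% by chance. siUSP9X replicate 2 stood apart from the other libraries: ribosomal protein genes took 2.15% of its counts against 4.48 to 5.19% in the other siUSP9X libraries, and the mitochondrial rRNA MT-RNR2, named after its value was seen, took 1.40% against 0.450 to 0.573%. Without that library 1674 genes were higher and 1620 lower, and these held all 1019 genes of the full comparison with the same sign. The counts fell without any 1 of the other 9 libraries. Without siCtrl replicates 1 to 5 there were 389, 198, 170, 192 and 218 higher genes and 375, 249, 189, 224 and 213 lower genes, and without siUSP9X replicates 1, 3, 4 or 5 there were 369, 345, 516 and 285 higher genes and 297, 280, 364 and 242 lower genes.

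The largest increases included the gap junction protein connexin 43 and a TGF-beta ligand. GJA1, which encodes connexin 43 (ENSG00000152661.8, chromosome 6, 121435577 to 121449727, plus strand), rose from 87.0 ± 7.86 to 286 ± 45.9 CPM (SD, n = 5 each), a log2 fold change of 1.71 ± 0.13 (SE, edgeR adjusted p = 5.63e-05). TGFB2, a secreted TGF-beta ligand, rose from 14.8 ± 3.40 to 56.7 ± 20.2 CPM (log2 fold change 1.94 ± 0.24), and DCP2, an mRNA decapping enzyme, from 38.1 ± 4.94 to 152 ± 65.1 CPM (1.99 ± 0.24). The bicarbonate cotransporter gene SLC4A7 rose by a log2 fold change of 1.58 ± 0.29, SYNE1, which links the nuclear envelope to the cytoskeleton, by 1.49 ± 0.30, and the cell adhesion gene NEGR1 by 1.76 ± 0.30. RBMS3, ZNF462, FIGN and NOVA2 completed the 10 largest increases, with log2 fold changes from 1.42 to 1.57. In siUSP9X replicate 2, DCP2, NEGR1, SLC4A7, RBMS3, ZNF462, SYNE1 and FIGN each lay far above the other siUSP9X libraries, and without that library the log2 fold change of ZNF462 was 0.85 and that of RBMS3 1.02. ZNF462, RBMS3 and SYNE1 kept their calls in 2, 6 and 7 of the 10 fits that left out 1 library. Among increases with the smallest p, the transcription factor ARID3A went from 31.0 ± 2.24 to 63.0 ± 2.82 CPM and TNFRSF11B, the decoy receptor osteoprotegerin, from 18.0 ± 1.54 to 39.9 ± 3.79 CPM.

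Beyond USP9X itself, the largest decreases were in membrane and secretory pathway genes. The tetraspanin CD81 fell from 160 ± 24.0 to 34.1 ± 10.4 CPM (log2 fold change -2.23 ± 0.22, edgeR adjusted p = 0.000403), and the calcium-binding protein gene S100A2 from 34.6 ± 5.53 to 7.59 ± 3.26 CPM (-2.19 ± 0.28). DDOST, a subunit of the oligosaccharyltransferase that glycosylates proteins in the endoplasmic reticulum, fell from 346 ± 26.2 to 108 ± 26.8 CPM, and CALU, a calcium-binding protein of the secretory pathway, from 535 ± 38.7 to 192 ± 36.6 CPM. The tetraspanin TSPAN1, the cytokine gene CSF3, the lysosomal fucosidase FUCA1 and EFHD2 fell by log2 fold changes of -1.65, -1.60, -1.56 and -1.44. Among decreases with the smallest p, MESD (ENSG00000117899.10, chromosome 15, 80946289 to 80989878, minus strand), a chaperone for the Wnt co-receptors LRP5 and LRP6, went from 62.6 ± 3.97 to 23.1 ± 1.83 CPM (log2 fold change -1.43 ± 0.10, edgeR adjusted p = 5.61e-05), and METTL9 from 106 ± 5.14 to 42.4 ± 3.33 CPM. Of the lower genes with an annotated 3′ UTR, 221 of 428 (51.6%) held at least 1 of the 7-base words AATCACA, AACTCTA, ATCACAA and CAACTCT, against 28.5% of the higher genes and 30.8% of genes that did not pass the threshold. These words were picked from the same fold changes. Among the genes just named, MESD, CALU, CD81, FUCA1 and METTL9 hold one, and DDOST, S100A2, TSPAN1, CSF3 and EFHD2 do not. Of the genes named as increased here and below, NEGR1, RBMS3, NOVA2, ZEB1, ZEB2, AJUBA and CTNND1 also hold one.

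Of 16 measured Wnt/beta-catenin target and feedback genes, none rose, 15 did not pass the threshold and 1 fell, TCF7L2, itself a transcription factor of the pathway (13.7 ± 1.41 to 8.26 ± 0.643 CPM, log2 fold change -0.73 ± 0.11). Adjusted over the list alone, 2 rose and 2 fell. At an unadjusted p under 0.05 edgeR gave 5 members, and 3 passed the threshold with DESeq2 and 1 with limma-voom. Of 17 members measured without siUSP9X replicate 2, 2 rose and 2 fell, while TCF7L2 alone was called when any other library was left out. LEF1, a target induced by the pathway, stood at 7.14 ± 1.30 CPM in siCtrl and 7.32 ± 1.09 CPM in siUSP9X (log2 fold change 0.04 ± 0.16). The feedback inhibitors NKD1 and ZNRF3 had log2 fold changes of 0.20 ± 0.21 and -0.12 ± 0.12, and the target TNFRSF19 -0.11 ± 0.21. AXIN2, a widely used readout of the pathway, was too low to test with all 10 libraries, with 61 counts over the 5 siCtrl libraries (0.608 CPM, exact 95% Poisson interval 0.465 to 0.781) and 48 over the 5 siUSP9X libraries (0.556 CPM, 0.410 to 0.737). Without siUSP9X replicate 2 it was tested, with a log2 fold change of -0.076 and an adjusted p of 0.916 (0.585 to 0.972 over the 8 alternatives that tested it). SOX17, an endothelial transcription factor, had 0 and 1 counts, and 0 counts allow up to 0.0367 CPM. The set test against other genes gave an adjusted p of 0.569 (limma camera). The test of the list on its own (limma fry) gave an adjusted p of 0.226 for a shared direction. For changes in either direction fry gave 7.08e-06, so some members differed between the groups.

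Among 32 measured Wnt receptors and transducers, 1 rose, 2 fell and 29 did not pass the threshold. The Wnt receptor gene FZD6 rose (log2 fold change 0.59 ± 0.15, SE), while FZD1 and FZD4 fell (-0.57 ± 0.13 and -0.41 ± 0.10). FZD4, a receptor with a known part in brain vessel growth, went from 9.61 ± 0.175 to 7.21 ± 0.489 CPM. The calls of FZD4 and FZD6 held in 2 of the 10 fits that left out 1 library, without siUSP9X replicates 2 or 3 for FZD4 and 2 or 4 for FZD6, and that of FZD1 in 8. Leaving out siUSP9X replicate 2 gave 5 higher and 4 lower members, and leaving out another library 0 to 1 higher and 0 to 2 lower. Beta-catenin mRNA, CTNNB1, had a log2 fold change of 0.17 ± 0.23 with all libraries and -0.16 without siUSP9X replicate 2, where it reached 807 CPM against 340 to 373 CPM in the other siUSP9X libraries. LRP6 had 0.54 ± 0.26 with all libraries and 0.22 without siUSP9X replicate 2. The set test gave an adjusted p of 0.551 (limma camera), and adjusted over the list alone 1 rose and 2 fell. The test of the list on its own (limma fry) gave 0.1798 for a shared direction and 0.0428 for changes in either direction. The 3′ UTRs of TCF7L2, FZD1 and FZD4 hold 1 or more of the 4 words named above, with AATCACA, ATCACAA and CAACTCT in TCF7L2. Words are common in these lists, in 17 of the 32 measured receptors and transducers and 5 of the 16 Wnt targets. CTNNB1 and LRP6, which did not pass the threshold, hold one too.

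Of 19 measured blood-brain barrier genes, ABCB1, the efflux pump P-glycoprotein, rose (32.8 ± 1.69 to 53.7 ± 16.8 CPM, log2 fold change 0.71 ± 0.17), none fell and 18 did not pass the threshold. ABCB1 was 83.3 CPM in siUSP9X replicate 2, and its log2 fold change without that library was 0.50. The call of ABCB1 held without siUSP9X replicates 2, 3 or 4 and was lost without any 1 of the other 7 libraries (adjusted p up to 0.161 over the alternatives). Leaving out siUSP9X replicate 2 gave 3 higher and 3 lower members, and leaving out another library 0 to 1 of each. The glucose transporter SLC2A1 (GLUT1) had a log2 fold change of 0.15 ± 0.13, and the lipid transporter MFSD2A, near 1 CPM in both groups, -0.14 ± 0.41. With p adjusted over the list alone, 3 rose and 2 fell, and the set test gave an adjusted p of 0.446 (limma camera). The test of the list on its own (limma fry) gave 0.129 for a shared direction and 0.0258 for changes in either direction. CLDN5, the main claudin of brain endothelium, had 22 counts in the 5 siCtrl libraries together and 6 in siUSP9X. It was too low to test with the filter.

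Of 22 measured tight and adherens junction genes, 3 rose, 2 fell and 17 did not pass the threshold (limma camera adjusted p = 0.569). The test of the list on its own (limma fry) gave 0.3705 for a shared direction and 0.000581 for changes in either direction. Claudin 1 mRNA (CLDN1) rose from 1049 ± 73.2 to 1650 ± 314 CPM, JAM2 rose by a log2 fold change of 0.81 ± 0.21, and CTNND1, which encodes p120 catenin and was named after its value was seen, by 0.63 ± 0.17. CLDN11 fell from 227 ± 28.3 to 116 ± 8.02 CPM (log2 fold change -0.97 ± 0.11), and F11R, which encodes JAM-A, from 30.6 ± 2.83 to 18.8 ± 3.34 CPM. The 3′ UTR of CLDN11 holds a word and that of F11R does not. OCLN and TJP1, which encode occludin and ZO-1, had log2 fold changes of 0.21 ± 0.16 and 0.37 ± 0.20, and of 0.044 and 0.12 without siUSP9X replicate 2. Adjusted over the list alone, 3 rose and 3 fell, and with 1 library left out 1 to 4 rose and 1 to 3 fell. JAM2 kept its call in 3 of these 10 fits and F11R in 9. Of 6 measured fenestration, caveola and transcytosis genes, 0 passed the threshold with edgeR and 0 adjusted over the list alone, against 1 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom. Without siUSP9X replicate 2, 2 of them rose (limma camera adjusted p = 0.446 with all libraries). The test of this list on its own placed it higher with all libraries (limma fry adjusted p = 0.00733). PLVAP, a protein of fenestrated endothelium, had 2 counts in each group.

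Many endothelial genes were near zero in both groups. Of 26 general endothelial genes, 17 were too low to test, among them PECAM1 (8 counts over the 5 siCtrl libraries, or 0.0797 CPM with an exact 95% Poisson interval of 0.0344 to 0.157), KDR (4 counts) and VWF (5 counts). ESAM, PROCR, ENG and EGFL7 were well measured, at 163, 90.6, 85.0 and 28.0 CPM over the pooled siCtrl counts, and these 4 and VWF were named after their values were seen. CDH5, which encodes VE-cadherin, had 53 counts in siCtrl and 74 in siUSP9X, a log2 fold change of 0.68 ± 0.34. Of 9 measured members 0 passed the threshold with edgeR, 3 were lower adjusted over the list alone, 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom gave 3 and 1. Without siUSP9X replicate 2, 4 members fell, and 0 to 1 without another library. The set test placed the list lower (limma camera adjusted p = 0.0415), with an adjusted p = 0.493 with an estimated correlation and 0.188 without siUSP9X replicate 2 (0.0156 to 0.328 over the alternatives). Intervals cover counting error only.

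**Figure D2:**
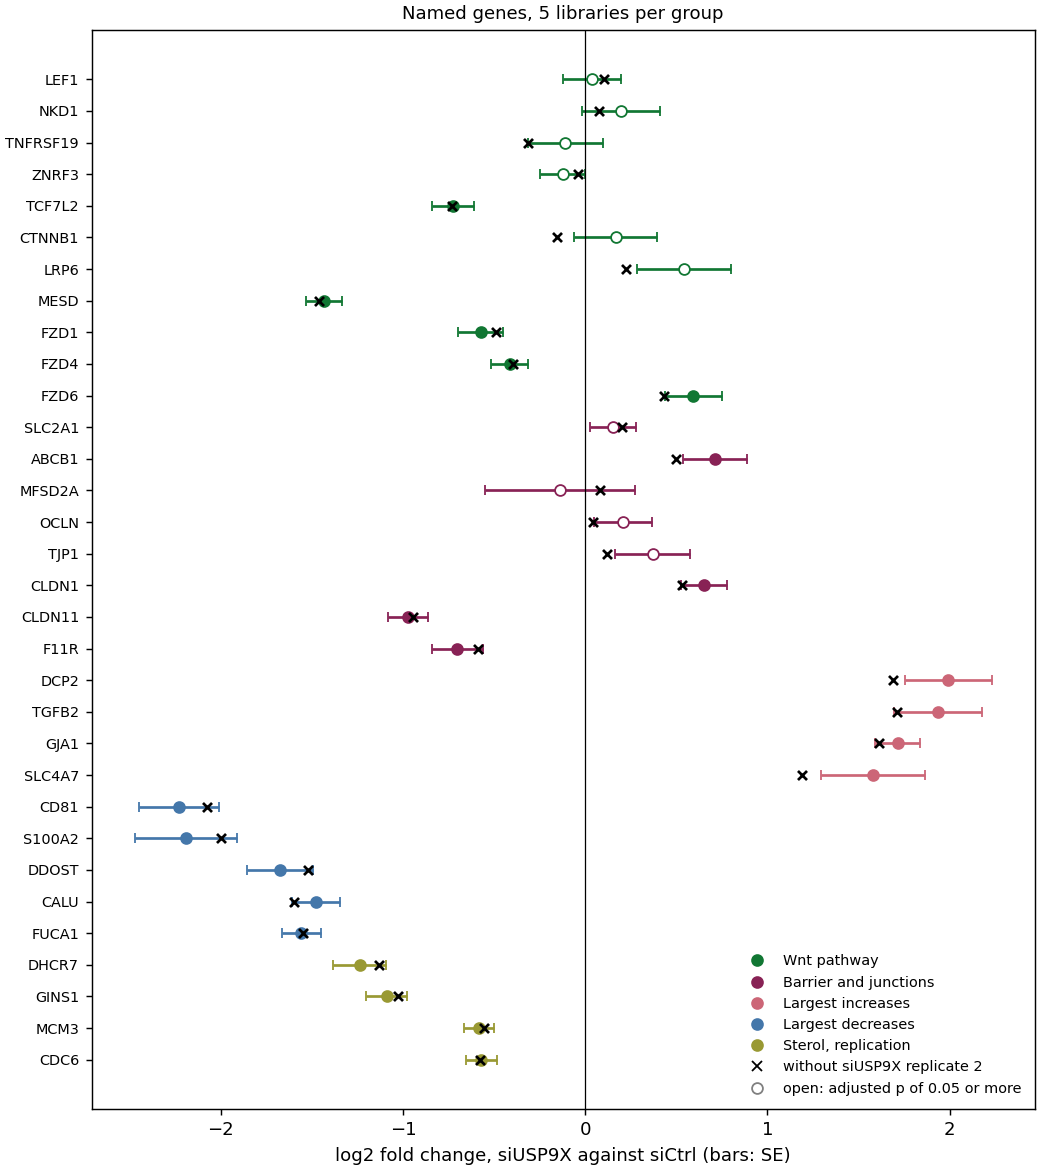
Log2 fold changes of 32 named genes in siUSP9X against siCtrl, 5 libraries per group, with SE (bars). Filled points have an edgeR adjusted p under 0.05, open points do not, and crosses give the value without siUSP9X replicate 2, as for CTNNB1 at -0.16 against 0.17.

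Most markers of other cell types were low, while the keratin genes KRT8 and KRT18 and the gene MBP were not. MBP, a myelin protein gene named after its value was seen, stood at 91.2 ± 5.98 CPM in siCtrl and 84.95 ± 13.5 CPM in siUSP9X. KRT8 and KRT18 stood at 2156 ± 239 and 1580 ± 113 CPM in siCtrl and fell to 1581 ± 189 and 946 ± 101 CPM in siUSP9X (log2 fold changes -0.45 ± 0.12 and -0.74 ± 0.10). The remaining 3 of the 5 measured epithelial markers did not pass the threshold, and adjusted over the list alone 4 were lower. There were 4 lower without siUSP9X replicate 2 and 1 to 2 without another library, and KRT8 kept its call in 3 of these 10 fits. Epithelial markers as a set were lower (limma camera adjusted p = 0.00448), with an adjusted p = 0.111 with an estimated correlation. The keratins KRT5, KRT14 and KRT19, named after their values were seen, had 0, 0 and 5 counts in siCtrl. Few members of the other lists were measured, 2 of the pericyte and smooth muscle, 2 of the fibroblast, 3 of the astrocyte, neuron and oligodendrocyte and 2 of the leukocyte and microglia markers, and 0 passed the threshold with edgeR, 0 adjusted over each list alone and 0 with DESeq2 or limma-voom. At an unadjusted p under 0.05 there was 1, the smooth muscle myosin gene MYH11, named after its value was seen. The neural set test gave an adjusted p of 0.752 (limma camera), the other 3 lists were too small for one, and 0 lymphatic endothelial markers were measured.

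Of 21 measured cholesterol synthesis and uptake genes, 9 fell, none rose and 12 did not pass the threshold, and adjusted over the list alone 12 fell. The set test placed the list lower (limma camera adjusted p = 6.28e-09), with an adjusted p = 0.111 with an estimated correlation. DHCR7, which encodes a reductase at the end of the synthesis pathway, went from 268 ± 21.7 to 114 ± 23.3 CPM (log2 fold change -1.24 ± 0.15). CYP51A1, a sterol demethylase, fell by a log2 fold change of -0.99 ± 0.15 and ACAT2, which makes acetoacetyl-CoA, by -0.65 ± 0.10. Of the 9 lower members 6 hold at least 1 of the 4 words in the 3′ UTR, DHCR7, CYP51A1 and ACAT2 among them, and among genes without them the set test gave an adjusted p of 0.00413, the highest of 23 alternatives. Without siUSP9X replicate 2, 16 members fell, and 5 to 9 without another library.

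Of 25 measured genes of the G1/S transition and DNA replication, 11 fell, 1 rose and 13 did not pass the threshold, and adjusted over the list alone 15 fell and 1 rose. The set test placed the list lower, with an adjusted p of 1.09e-07 (limma camera), and an adjusted p = 0.0869 with an estimated correlation. Leaving out siUSP9X replicate 2 gave 16 lower and 1 higher, and leaving out another library 6 to 9 lower and 0 higher. GINS1, part of the replicative helicase, went from 83.1 ± 6.40 to 39.1 ± 4.68 CPM (log2 fold change -1.09 ± 0.11). The helicase subunit MCM3, the licensing factor CDC6 and UHRF1, which maintains DNA methylation, fell by -0.58 ± 0.08, -0.57 ± 0.09 and -0.83 ± 0.14. CCNE1, cyclin E1, rose by 0.46 ± 0.12 (named after its value was seen). Of the 11 lower members 5 hold a word, GINS1, MCM3, CDC6 and UHRF1 among them, and among genes without the words the set test gave an adjusted p of 0.0101, the highest of 23 alternatives. Of 28 G2/M and mitosis genes, the cyclins CCNA2 and CCNB2 fell (-0.53 ± 0.11 and -0.64 ± 0.11), both with AATCACAA in the 3′ UTR, and 26 did not pass the threshold (limma camera adjusted p = 0.191). The count adjusted over the list alone was 3 lower. CCNA2 lost its call without siCtrl replicate 3 or siUSP9X replicate 5. Without siUSP9X replicate 2, 9 of the G2/M genes fell and the set test gave an adjusted p of 0.00189 (0.00112 to 0.507 over the alternatives).

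Of 22 measured TGF-beta and BMP pathway genes 8 rose, 1 fell and 13 did not pass the threshold, and adjusted over the list alone 10 rose and 3 fell. Leaving out siUSP9X replicate 2 gave 10 higher and 3 lower, and leaving out another library 3 to 6 higher and 0 to 1 lower. Besides TGFB2, the matrix protein TGFBI went from 26.6 ± 4.20 to 44.8 ± 5.98 CPM (log2 fold change 0.75 ± 0.14) and the ligand BMP6 from 6.45 ± 0.867 to 10.6 ± 1.08 CPM (0.72 ± 0.13). The inhibitory SMADs SMAD6 and SMAD7 rose by 0.84 ± 0.22 and 0.76 ± 0.19 (named after their values were seen). SKI, a repressor of SMAD signalling, fell by a log2 fold change of -0.48 ± 0.10, holds AATCACAA in its 3′ UTR and lost its call without siCtrl replicates 4 or 5. As a set the list was higher (limma camera adjusted p = 0.0113), with an adjusted p = 0.169 with an estimated correlation.

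Of 23 measured YAP/TAZ target genes 5 rose, none fell, 18 did not pass the threshold, and adjusted over the list alone 7 rose. These became 9 higher and 2 lower without siUSP9X replicate 2, and 2 to 5 higher and 0 lower without another library. AJUBA, LATS2 and WWC1 rose by log2 fold changes of 0.50 ± 0.08, 0.49 ± 0.10 and 0.38 ± 0.09 (WWC1 named after its value was seen), beside TGFB2 and RBMS3. The set test placed the list higher, with an adjusted p of 0.000403 (limma camera) and an adjusted p = 0.215 with an estimated correlation. The matrix signalling genes CTGF and CYR61, in the table under these symbols and so not counted under the newer symbols CCN2 and CCN1 of the list, were named after their values were seen. CTGF rose from 70.5 ± 3.83 to 139.6 ± 30.8 CPM, and CYR61, at 310 ± 14.1 CPM in siCtrl and 366 ± 114 CPM in siUSP9X, did not pass the threshold (log2 fold change 0.24 ± 0.21, adjusted p = 0.461). Among 15 mesenchymal transition and contractile genes, ZEB1 and ZEB2, transcriptional repressors of epithelial genes, rose by 0.99 ± 0.21 and 1.56 ± 0.36, none fell and 13 did not pass the threshold (limma camera adjusted p = 0.190). With p adjusted over the list alone, 3 rose, and the test of the list on its own placed it higher (limma fry adjusted p = 0.00733). Both ZEB genes hold a word and were highest in siUSP9X replicate 2. Without that library 6 members rose, 1 fell and the set test gave an adjusted p of 0.00426 (up to 0.432 over the alternatives). Without siCtrl replicates 2, 4 or 5 both ZEB genes lost their calls, as ZEB2 did without siCtrl replicate 3. Of 23 basement membrane and matrix genes COL5A2 and MMP10 rose, COL4A1 fell (151 ± 16.4 to 94.97 ± 18.9 CPM, with a word in its 3′ UTR) and 20 did not pass the threshold (limma camera adjusted p = 0.0642). The test of the matrix list on its own placed it higher (limma fry adjusted p = 0.0482). The counts adjusted over the list alone were 4 higher and 1 lower, and COL4A1 kept its call in 6 of the 10 fits that left out 1 library. In the 9 of these fits that kept siUSP9X replicate 2, 2 to 3 rose and 0 to 1 fell, and without it, when 9 rose, the set test gave an adjusted p of 0.0148 (0.00413 to 0.491 over the alternatives).

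Of 25 measured NF-kB and endothelial activation genes, the colony-stimulating factor genes CSF2 and CSF3 fell, none rose and 23 did not pass the threshold, while 8 fell and 1 rose adjusted over the list alone. There were 9 lower and 3 higher without siUSP9X replicate 2, and 2 lower and 0 to 1 higher without another library. CSF2 went from 5.09 ± 0.785 to 0.998 ± 0.638 CPM and CSF3 from 20.6 ± 1.54 to 6.78 ± 1.79 CPM. Activation genes as a set were lower (limma camera adjusted p = 0.00476), with an adjusted p = 0.435 with an estimated correlation. Of 22 interferon-stimulated genes 3 fell, STAT2 and OAS3 among them (log2 fold changes -0.34 ± 0.09 and -0.51 ± 0.14), none rose and 19 did not pass the threshold, and 4 fell adjusted over the list alone. There were 7 lower without siUSP9X replicate 2 and 1 without any other library, when STAT2 and OAS3 lost their calls. STAT2 and OAS3 hold a word in the 3′ UTR, among 10 of the 22 measured members that do. Interferon-stimulated genes as a set were lower (limma camera adjusted p = 0.00697), with an adjusted p = 0.136 with an estimated correlation and 0.114 among genes without the words, the highest of 23 alternatives. In siUSP9X replicate 2, OAS3 was higher than in the other siUSP9X libraries, at 254 CPM.

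Of 31 proteasome subunits PSMD13, PSMC4 and PSMD2 fell (log2 fold changes -0.54 ± 0.10, -0.50 ± 0.12 and -0.39 ± 0.10), none rose and 28 did not pass the threshold, and 6 fell adjusted over the list alone. The set test placed the list lower (limma camera adjusted p = 0.000110), with an adjusted p = 0.316 with an estimated correlation, and 14 fell without siUSP9X replicate 2 and 1 to 2 without another library, with PSMC4 and PSMD2 called in 3 and 1 of the 10 fits that left out 1 library. In the Notch list of 15 genes the ligand DLL4 fell from 3.07 ± 0.508 to 1.11 ± 0.381 CPM and the target HES4 from 23.2 ± 4.99 to 11.5 ± 3.99 CPM, while 13 did not pass the threshold (limma camera adjusted p = 0.569). Over the Notch list, 1 rose and 2 fell when adjusted over the list alone, and 2 rose and 3 fell without siUSP9X replicate 2, against 0 to 1 and 1 to 2 without another library, with HES4 called in 2 of these 10 fits. DLL4 and COL4A1 were the only called members of the 17 tip cell and angiogenesis genes (limma camera adjusted p = 0.987, with 2 higher and 2 lower adjusted over the list alone), and without siUSP9X replicate 2, 5 rose and 2 fell, against 0 and 1 to 2 without another library. Of 23 p53 targets the stress regulator SESN1 rose (0.73 ± 0.16) and FAS, DDB2 and FDXR fell (-0.83 ± 0.15, -0.55 ± 0.13 and -0.76 ± 0.20), as they did adjusted over the list alone (limma camera adjusted p = 0.446). There were 3 higher and 5 lower without siUSP9X replicate 2 and 0 to 1 higher and 1 to 3 lower without another library, with FDXR, DDB2 and SESN1 called in 3, 4 and 6 of these 10 fits. Of 28 unfolded protein and integrated stress response genes the disulfide isomerase PDIA6 fell (257 ± 5.85 to 164 ± 10.7 CPM) as it did adjusted over the list alone (limma camera adjusted p = 0.402), with 4 higher and 5 lower without siUSP9X replicate 2 and PDIA6 alone without any other library. Of 24 glycolysis and hypoxia-induced genes the neuronal-type glucose transporter SLC2A3 rose from 6.21 ± 0.582 to 15.4 ± 2.29 CPM and did so adjusted over the list alone (limma camera adjusted p = 0.569), with 4 higher and 1 lower without siUSP9X replicate 2 and SLC2A3 alone without any other library. For the deubiquitinases the set test gave an adjusted p of 0.446 (limma camera), and 2 rose and 2 fell adjusted over the list alone.

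**Figure D3:**
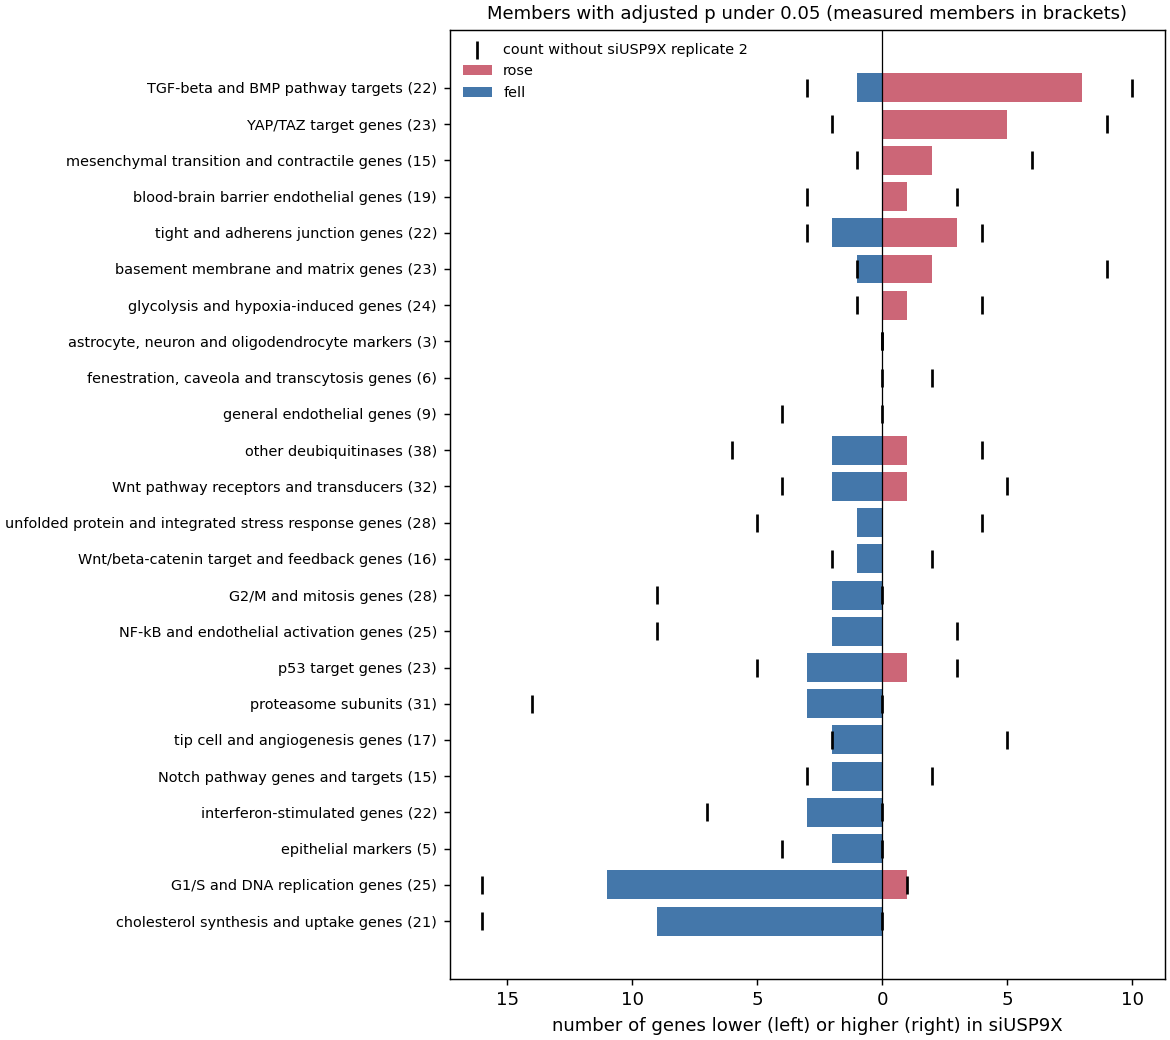
Members of 24 gene lists that were higher (right) or lower (left) in siUSP9X at an adjusted p under 0.05, as counts of genes, with measured members in brackets. Bars use all 10 libraries and ticks leave out siUSP9X replicate 2, with 9 lower cholesterol genes in the bar and 16 at the tick.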

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

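Of the tests below, those of a trend with transcript length and of a mislabelled library were chosen after the result was seen, and the offsets for length and GC content were chosen after the correlations with length and GC content had been seen. In 33 of 176 groups of 5 libraries, 1 library lay far from the other 4 by Dixon's test, where chance alone gives about 1 in 20. Of these, 30 were in siUSP9X replicate 2, as 26 genes and 4 library measures. Among the other 3, siCtrl replicate 4 had a total of 26.5 in units of 1e+06 counts against 17.7 to 18.8 in its group, DDB2 was 41.9 CPM in siCtrl replicate 1 against 47.4 to 49.1 CPM, and CSF2 was 2.11 CPM in siUSP9X replicate 3 against 0.498 to 0.863 CPM.

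In siUSP9X replicate 2 the total was 20.4 in units of 1e+06 counts, ribosomal protein genes took 2.15% of counts, MT-RNR2 took 1.40%, and the TMM factor was 0.885 against 1.02 to 1.04 in the rest of its group. Genes above the rest of the group there were DCP2 at 266 CPM, NEGR1 at 31.4, SLC4A7 at 945, RBMS3 at 55.2, ZNF462 at 269, SYNE1 at 94.5, FIGN at 152, ABCB1 at 83.3 and CLDN1 at 2189 CPM. ZEB1 at 61.5, ZEB2 at 12.8, OAS3 at 254, FAS at 49.6, PSMD2 at 489, USP48 at 171, CTNNB1 at 807, LRP6 at 114, OCLN at 45.3 and TJP1 at 260.1 CPM were above it too. Genes below it were DDOST at 60.6 CPM, F11R at 12.9, HES4 at 4.54, UHRF1 at 48.9, PDIA6 at 146, PSMC4 at 79.0 and KRT18 at 768 CPM.

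A siCtrl library with a wrong label is argued against by USP9X itself, at 68.8 CPM in this library and 283.3 CPM in the lowest siCtrl library. Across genes its log2 difference from the rest of its group went with transcript length (Spearman rho 0.545) and GC content (rho -0.660), slightly more than in any other library, where the largest were -0.517 and -0.654. Genes are not independent replicates, so these are descriptions of the library. After offsets removed the trends, the SD of its log2 differences went from 0.981 to 0.659, against at most 0.305 in the other 9 libraries, so the trends may account for part of its distance and not for all of it. RNA quality and a difference between cultures stay open, and no biological explanation was tested, since the labels give this library the same treatment as the other 4.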

How the results depend on the processing

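The alternatives with offsets for length and GC content, library weights, the block without replicate number 2 and genes without the 4 words were chosen after seeing the data. USP9X stayed lower and past the threshold in all 23 alternatives (log2 fold change -3.82 to -3.14, adjusted p at most 0.0236). The 570 higher and 449 lower genes became 1127 and 979 with DESeq2, 2722 and 2733 with 1 surrogate variable, 1568 and 1569 with length and GC offsets, 2476 and 2445 with limma-voom and library weights, and 366 and 208 among the 8159 genes without the 4 words, where fewer genes were counted. They were 102 and 136 at an adjusted p under 0.01 and 136 and 80 with an absolute log2 fold change of at least 1, both stricter by construction. Leaving out 1 library gave 170 to 1674 higher and 189 to 1620 lower genes, the lowest without siCtrl replicate 3 and the highest without siUSP9X replicate 2. In every alternative, 0 of the 1019 genes were called with the opposite sign. Library totals gave 61.6% of calls higher, and the other scalings 54.7% and 55.1%. With the replicate block there were 34 higher and 57 lower genes, all among the 1019, and 1582 and 1856 with the replicate block and replicate number 2 left out of both groups. The libraries share only a number: same-numbered libraries had correlations of -0.367, -0.419, -0.029, 0.228 and -0.038, and 1 of 10 libraries correlated best with its own number. Of 73 genes past the threshold that the rule for named genes selects, 46 kept it whichever library was left out, 25 kept it with the replicate block, and 14 lost it without the filter. STAT2, OAS3 and PSMD2 kept it in 1 of the 10 fits that left out a library, and FZD4, FZD6, HES4, USP48 and ZNF462 in 2. The sign turned for 4 genes not past the threshold, and the cause was not tested. The surrogate variable was 0.905 in siUSP9X replicate 2 and -0.233 to 0.136 in the other libraries. The weight of that library was 0.047, against 0.499 to 2.69 in the others. Both alternatives thus leaned little on siUSP9X replicate 2, where CTNNB1 was highest, and come close to leaving it out. CTNNB1 was -0.094 with 1 surrogate variable, -0.081 with offsets, -0.15 with library weights, -0.19 with the block without replicate number 2 (adjusted p = 0.0324, range 0.0324 to 0.857) and -0.16 to 0.25 with 1 library left out. MFSD2A was 0.041, 0.035, 0.077 and 0.22 in the same 4 alternatives and -0.33 to 0.080 with 1 library left out, OCLN was -0.14 with offsets and -0.039 with the block without replicate number 2, and LEF1 was -0.046 to 0.11 with 1 library left out. LRP6 and TJP1 passed the threshold with 1 surrogate variable (adjusted p = 0.0227 and 0.0319, ranges to 0.664 and 0.813). The camera set tests of Wnt targets (adjusted p 0.420 to 0.939) and barrier genes (0.334 to 0.584) stayed on their side of the threshold in all alternatives. The call for endothelial genes was lost in 15 (0.0512 to 0.328), that for interferon genes among genes without the words (0.114) and that for epithelial markers with offsets (0.0549). G2/M, mesenchymal and matrix genes each passed in 5 (0.00112 to 0.0423, 0.00426 to 0.0301 and 0.00413 to 0.0342). AXIN2, CLDN5 and 17 of the 26 endothelial genes had too few counts for the filter with all 10 libraries. AXIN2 did not pass the threshold in the 8 alternatives that tested it (log2 fold change -0.32 to -0.026, adjusted p 0.585 to 0.972), nor CLDN5 without the filter (-1.51, adjusted p = 0.365, its 1 alternative).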

Other observations

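Of the tests below, those of the siRNA duplex, of too few counts and of a minority of other cells were chosen after the result was seen, and the gene families and genes of this paragraph and the next were chosen after their values were seen. Of 18 histone genes measured at a mean of at least 3 CPM, 4 rose and 0 fell with edgeR (median log2 fold change 0.40, and 0.38 to 0.40 with other scalings, where 2 to 4 rose), and 12 rose without siUSP9X replicate 2. Of 9 ARID genes, which encode DNA-binding proteins, 3 rose and 0 fell with each scaling, with 6 higher without that library. Of 9 MCM genes 3 fell and 0 rose (2 fell with library totals), and 7 fell without that library. For 8 CCT chaperonin genes, 23 mitochondrially encoded genes and 5 metallothionein genes edgeR called 0, with 2, 3 and 2 at an unadjusted p under 0.05, and 1 metallothionein gene lower with DESeq2 size factors. Without siUSP9X replicate 2, 4 CCT genes fell, 1 mitochondrially encoded gene rose, and 1 metallothionein gene rose and 2 fell.

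EPAS1, which encodes the hypoxia-inducible factor HIF-2 alpha, rose from 152 ± 16.3 to 300.5 ± 17.5 CPM (SD, n = 5 each, log2 fold change 0.99 ± 0.10, SE, edgeR adjusted p = 0.000405). CITED2, a transcriptional co-regulator that competes with HIF, rose from 53.4 ± 1.55 to 128 ± 29.5 CPM, and the cell cycle inhibitor CDKN2B from 6.46 ± 0.633 to 14.5 ± 3.24 CPM. SCD, the stearoyl-CoA desaturase, fell from 539 ± 32.7 to 223 ± 49.6 CPM and FOXM1, a transcription factor of mitotic genes, from 152 ± 13.9 to 90.5 ± 5.79 CPM. PRKAR1A, MYCBP and DYNLT1 fell by log2 fold changes of -1.33, -1.35 and -1.20. LRP5, the Wnt co-receptor, had a log2 fold change of 0.03 ± 0.13.

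A hypothesis for part of the lower genes is silencing through the seed sequence of the siRNA, which pairs with short words in 3′ UTRs. The word AATCACA had the most negative standardized effect, -12.43 (mean log2 effect -0.13 over 1710 genes, negative in 5 of 5 siUSP9X libraries), against -5.40 in the lowest of 100 shuffles, and AACTCTA had -11.74, which rests on the adjustment for UTR length, GC content and mean CPM, since the unadjusted median log2 fold change was 0.10 for genes with at least 1 of the 4 words and -0.020 for genes with none, though 5.90% and 2.54% of them fell. That both words come from target sites in USP9X is argued against, since 1 of the 2 8-base words, CAACTCTA and not AATCACAA, is in the USP9X mRNA, while both strands of 1 duplex may account for both: the stretch CTGTGATTCAGCAACTCTA (chromosome X, 41201165 to 41201183, plus strand, GRCh38, coding part of exon 31) holds CAACTCTA and the reverse complement of AATCACA, an arrangement found in 0 others of the 752 mRNAs with CAACTCTA. MESD, CALU, CD81, COL4A1, SKI, CCNA2, CCNB2 and TCF7L2, the only Wnt target called with all 10 libraries, hold an 8-base word. NEGR1, which rose, holds one too. The decrease of the lower genes among these could come from the siRNA sequence and not from the loss of USP9X. These libraries cannot separate the 2, as the siRNA sequence is not in the labels and no second siRNA or rescue was analysed here. In all 111 words lay below the lowest shuffle, among them AGGCTGG at -8.15 and AAACTCT, which overlaps AACTCTA, at -7.86. Without siUSP9X replicate 2 the 4 words ranked 1 to 4 from the most negative, with AATCACA at -14.91 and AACTCTA at -15.04. AGGCTGG went to -6.15 there, at rank 17. In the full comparison 207 genes without the 4 words, USP9X not counted, were also lower, so the words leave part of the decreases open.

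Endothelial genes near zero in cells labelled endothelial were also weighed. Too few counts is argued against, since 19 of the 26 genes had an upper 95% limit under 1 CPM over the pooled siCtrl counts. A minority of other cells among endothelial ones is argued against too, since it would lower endothelial genes by less than 2-fold and 17 of the 26 genes stayed under 1 CPM with that limit doubled. The median of the endothelial genes (0.06 CPM) was just over 0.1 times that of the epithelial markers (0.568 CPM), the level set for such a mixture, so this comparison does not argue against it. The argument rests on the doubled limits, which concern dilution as the reason for the low values. These limits cannot exclude that some other cells were present. KRT8 and KRT18 were at 2158 and 1588 CPM, but the other epithelial markers were far lower. ESRP1, CLDN4, EPCAM and CDH1 had 5.75, 1.01, 0.907 and 0.229 CPM in pooled siCtrl counts, and GRHL2 had 0 counts (named after their values were seen). The 2 keratins therefore do not show an epithelial identity. A line that has lost endothelial genes, or one of another identity than its label, stays open.

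Chance in how libraries fell into groups is argued against for the count of changed genes, and not excluded. Of 100 splits of the 10 libraries into 5 and 5, out of 126 possible, 1 gave as many genes, the real one with 1019, and the highest of the others gave 0. Every other split puts siCtrl and siUSP9X libraries into the same group, which widens the spread within groups, so low counts there were likely beforehand. A difference between cultures or batches that goes with the groups is not tested by these splits.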
